A study of Homo sapiens with 6 samples.

How the data were processed

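Gene expression was measured on Affymetrix whole-transcript arrays in A549 cells, an established human lung adenocarcinoma line. Per the labels' protocols, cells were grown with 10% serum and transfected on 2 occasions, 24 h apart, with 40 nM siRNA, and cDNA was made from 300 ng of total RNA. There were 6 arrays, 3 from cells given a pool of siRNAs against the long noncoding RNA CONCR and 3 from cells given a control siRNA. The series describes the 3 knockdowns as independent. It does not say whether they came from separately grown cultures, so p-values measure only the spread between these samples, which may be partly technical.

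The deposited values are log2 signals. Per the submitters' processing notes they were made by RMA, a background correction, quantile normalization and median-polish summary across probes, with Affymetrix Power Tools, whose version is not given in the sources used here. The genome build of the probe sets is not given in the sources used here either, so no coordinates are printed. Quantile normalization forces the arrays to nearly equal distributions, so a change in the total amount of RNA per cell could not be seen in these values. Array signals have no read depth, and the number of arrays limits the precision.

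The deposited matrix held 70523 probe sets. Of these, 2995 were taken as control probe sets from the form of their identifiers (spike-ins, background probes, numbered and exon-level control sets) and left out of the comparison, because no annotation marked them, and 67528 were transcript clusters. A transcript cluster was tested when its log2 signal exceeded 4 (a linear signal of 16) on at least 3 of the 6 arrays, which left 32540 and removed 34988. Among the tested clusters, 994 lay on alternate haplotype scaffolds and 1555 had values identical to another cluster. Gene symbols came from the platform annotation supplied with the series. It named 25324 probe sets, 23781 with 1 symbol and 1543 with several. Of the former, 21497 were matched by Entrez identifier to an NCBI RefSeq gene list of assembly GRCh38.p14 and took its symbol. Another 306 without such a match had an older symbol, which was updated where the list gave it as a former name of exactly 1 gene. Of the tested clusters, 16368 had 1 symbol, 1131 had several and 15041 had none here. A gene was named only from a probe set with 1 symbol, and the brightest probe set stood for a gene with more than 1, giving 15497 genes.

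Groups were compared with limma 3.58.1 in R 4.3.3 (with the data.table package, version 1.17.8), using lmFit and eBayes with no trend and no robust option, two-sided, with Benjamini-Hochberg adjustment over all tested probe sets and a threshold of 0.05. Moderation gave 6.91 degrees of freedom. Every adjusted p for a gene below is from this fit. Log2 fold changes are CONCR siRNA minus control siRNA. Single values of CONCR and DDX11 were also compared by a two-sided exact permutation test, whose smallest possible p with 3 arrays against 3 is 0.1.

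A set of 23 gene lists was written from textbook knowledge before the data were examined, covering the cell cycle, the damage response, stress pathways, the lung epithelial lineage, the neighbourhood of CONCR, and markers of fibroblasts, leukocytes and endothelium. Each list was tested against the other genes with limma's camera at a preset correlation between genes of 0.01, and again with an estimated correlation. It was also tested with fry, which asks whether the members move one way on balance and does not compare them with other genes. Adjustment was over the 23 lists.

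The genes to be named were also fixed by a rule before the data were examined. The rule took CONCR and DDX11, the 12 genes with the largest positive and the 12 with the largest negative log2 fold change among called genes whose 2 groups of arrays did not overlap (without small RNA genes, open reading frame symbols and antisense symbols), and up to 4 members of each list with the smallest p. Of the list members, those with an unadjusted p of 0.05 or more are not named. Genes outside the rule were chosen after their values were seen, and are E2F8, RRM2, NCAPH, CASP2, E2F1, E2F7, GDF15 and the genes of the closing observations.

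The fit was tested on simulated data before use. Over 10 runs with 200 changed probe sets among 32540, given the observed spread, it recovered 2.39% of changes of 0.3 log2 units, 38.4% of changes of 0.5 and 88.9% of changes of 1, with a mean of 3.2 false calls per run (3.59% of calls). A list of genes moved together by -0.1 was called lower in 10 of 10 runs over 15497 genes, and no list left in place was called. Simulated genes varied independently of one another, so this run says nothing about correlated genes.

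The alternatives were the replicate number as a block, no filter, a strict filter at a log2 signal of 6, quantile normalization, median centring, an intensity trend with robust estimation, array weights, an unmoderated statistic, leaving out each array, a 1.5-fold minimum, the log odds, 1 probe set per gene, and for the lists an estimated correlation, fry and the mean over the probe sets of a gene. A correction for gene length and leaving out each array for the lists were added after the data were seen. For the length correction, each array's deviations from the probe-set mean were fitted by loess (span 0.5) on gene length from the RefSeq table. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.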

Results

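The transcriptome of A549 lung adenocarcinoma cells was compared between cells transfected with a pool of siRNAs against the long noncoding RNA CONCR and cells transfected with a control siRNA, on 3 arrays each. CONCR, whose gene symbol is DDX11-AS1, is transcribed divergently from DDX11, which encodes a DNA helicase of sister chromatid cohesion, and the study asked what the RNA does in cohesion. The median log2 signal over transcript clusters lay between 3.83 and 3.89 on the 6 arrays. Correlations between arrays across tested transcript clusters were 0.989 to 0.993 within a group and 0.987 to 0.991 between groups.

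The targeted RNA was measured first. The CONCR probe set (DDX11-AS1) had a log2 signal of 4.46 ± 0.21 (SD, n = 3) with CONCR siRNA and 4.69 ± 0.04 (SD, n = 3) with control siRNA. The difference was -0.23 (SE 0.10, 95% confidence interval -0.48 to 0.01), and it did not pass the test (limma adjusted p = 0.42, two-sided exact permutation p = 0.1, the smallest this design allows). On the single arrays the signal was 4.23, 4.49 and 4.64 with CONCR siRNA against 4.71, 4.71 and 4.64 with control siRNA. Without CONCR siRNA replicate 1 the difference was -0.12. The mean signal of the probe set, 4.57, lay not far above the filter's log2 signal of 4. It was at percentile 61.6 of all 67528 transcript clusters, a ranking that includes the 34988 removed by the filter. As the difference did not pass, it does not check the labels. Its fold of 1.17 lower is on the RMA scale.

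DDX11, the neighbouring helicase gene, had nearly equal signals of 6.33 ± 0.03 with CONCR siRNA and 6.34 ± 0.02 with control siRNA (SD, n = 3). The log2 difference for DDX11 was -0.02 (SE 0.05, 95% confidence interval -0.13 to 0.10, limma adjusted p = 0.94, exact permutation p = 0.4). A second probe set, annotated to both DDX11 and its near copy DDX12P, differed by -0.04 (SE 0.06, limma adjusted p = 0.85), and its signal cannot be assigned to 1 of them. Among 9 measured genes near CONCR on the short arm of chromosome 12, none passed over all probe sets. BICD1, a dynein adaptor gene, was at -0.31 (SE 0.06, limma adjusted p = 0.053) and was the 1 gene that passed when adjusted over the list alone. SINHCAF was at 0.20 and RESF1 at 0.27, with adjusted p of 0.22 and 0.33 from limma.

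**Figure D1:**
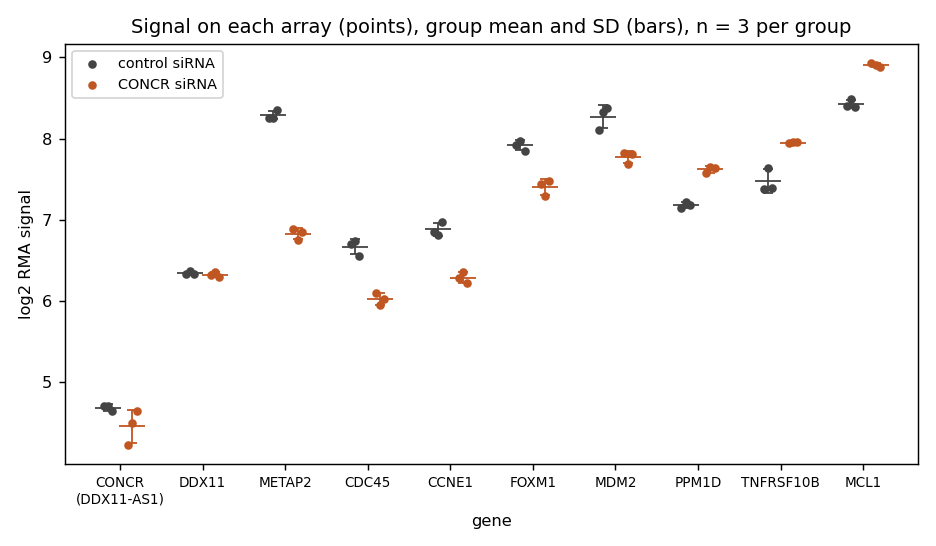
Log2 RMA signal (vertical axis) of 10 genes (horizontal axis) on each of the 3 control siRNA arrays (grey) and 3 CONCR siRNA arrays (orange), with points for arrays and bars for the group mean and SD. CONCR differed by -0.23 with 1 low CONCR siRNA array at 4.23, DDX11 by -0.02, and METAP2 by -1.46 with no overlap between groups.

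Among called probe sets more fell than rose with CONCR siRNA, while the median log2 change over all tested probe sets was 0.01. METAP2, a methionine aminopeptidase, had the largest fall at -1.46 (SE 0.06, n = 3 per group, 2.75-fold lower), followed by CEMIP2, a transmembrane hyaluronidase, at -1.40 (SE 0.07) and PSMD10, the oncoprotein gankyrin of the proteasome regulatory particle, at -1.28 (SE 0.09). ARHGAP19, a RhoA GTPase-activating protein, had the largest rise among named genes at 0.85 (SE 0.05, 1.81-fold higher). Of 32540 tested probe sets, 613 passed an adjusted p of 0.05 in limma, 125 higher and 488 lower. A fold of at least 1.5 was reached by 10 of the higher and 164 of the lower ones, and 31 probe sets were at least 2-fold lower while 0 were 2-fold higher by the same limma test. An unadjusted p under 0.05 was found for 4146 probe sets, and the arrays of the groups did not overlap for 19.1% of probe sets, against 10% by chance.

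The other strong falls were in genes of varied function. NEK7, a mitotic kinase and partner of the NLRP3 inflammasome, was lower by 2.30-fold (log2 -1.20, SE 0.06). RDH11, a retinol dehydrogenase, was at -1.19 (SE 0.06) and RAB31, a GTPase of endosomal traffic, at -1.14 (SE 0.05). USP46, a deubiquitinase, fell by 1.12 and SF3B6, a subunit of the U2 snRNP, fell by 1.09. CDC27, a core subunit of the anaphase-promoting complex, was at -1.05 (SE 0.08), APOO, a protein of the mitochondrial cristae, at -1.04 and SUDS3, a subunit of the Sin3 deacetylase complex, at -1.02. PRKCA, protein kinase C alpha, went from 9.76 to 8.77 (log2 -0.99, SE 0.09). Limma adjusted p for these 9 genes and the 3 above ran from 0.0014 for METAP2 to 0.0088 for SF3B6. Leaving out any 1 array kept the call of 11 of the 12, and SF3B6 lost it without control siRNA replicate 2 or 3, with an adjusted p of at most 0.051.

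Genes that rose did so by less. The intronic noncoding transcript KCNQ5-IT1 was at 0.82 (SE 0.14), TP53INP1, a p53-induced regulator of autophagy and cell death, at 0.73 (SE 0.12), TMC7 at 0.71 (SE 0.08) and GLDC, the glycine decarboxylase of the glycine cleavage system, at 0.64 (SE 0.07). HBEGF, a ligand of the EGF receptor, rose by 0.63 and SDC4, the proteoglycan syndecan 4, by 0.58. MLKL, the executioner of necroptosis, was higher by 0.57, NCEH1, a cholesterol ester hydrolase, by 0.56, and ARSJ, SUCO and the metal-binding MT2A by 0.56 each. Adjusted p for these 12 genes, ARHGAP19 included, ran from 0.0026 for ARHGAP19 to 0.043 for KCNQ5-IT1 by limma. ARHGAP19, TMC7, GLDC, HBEGF and NCEH1 were called without each array in turn too. KCNQ5-IT1 lost its call whichever array was left out, its adjusted p reaching 0.13.

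Over genes with 1 probe set each, 405 of 15497 passed the limma test adjusted over all probe sets, 93 higher and 312 lower. Fitted and adjusted alone, the same genes gave 958 calls, 304 higher and 654 lower. Protein-coding genes made up 391 of the 405. Long noncoding RNA genes gave 5 calls among 765, and pseudogenes 8 among 932, all 8 lower. A further 192 called probe sets had no gene symbol here and 14 had several, and these stay unnamed. The median absolute log2 change was 0.41 among higher and 0.49 among lower probe sets. The number of calls depended on the arrays, with 129 without control siRNA replicate 2 and 411 without control siRNA replicate 1, and 105 of the 613 calls were made without each array in turn.

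**Figure D2:**
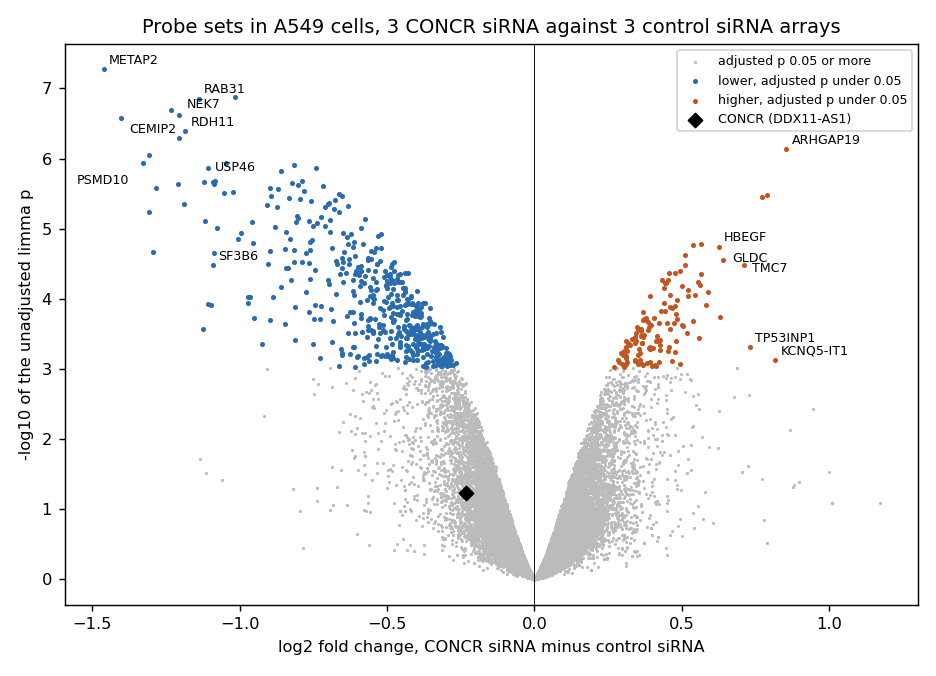
Log2 fold change (horizontal axis) against -log10 of the unadjusted limma p (vertical axis) for 32540 probe sets. Blue and orange points passed an adjusted p of 0.05, 488 lower and 125 higher, and the black diamond marks CONCR at -0.23.

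Of 46 measured genes of DNA replication and of the G1/S transition, 6 fell after CONCR siRNA. DTL, a substrate receptor of the CRL4 ubiquitin ligase, fell by 0.68 (SE 0.05), CDC45, a part of the replicative helicase, by 0.64 (SE 0.07), CCNE1, the S-phase cyclin E1, by 0.60 (SE 0.07) and UHRF1, which guides maintenance DNA methylation, by 0.43 (SE 0.05), n = 3 per group. The adjusted p of DTL was 0.0036 and that of UHRF1 0.015 in limma. E2F8 (-0.40) and RRM2 (-0.31), the small subunit of ribonucleotide reductase, fell too, with a second, dimmer RRM2 probe set at -0.14. E2F1 was at -0.33 with an adjusted p of 0.065 by limma. None rose and 40 did not pass, with 8 lower when adjusted over the list alone and 41 with a negative sign. The list median was -0.07, and the list was lower than other genes by camera (adjusted p = 2.8e-07), with adjusted p = 0.44 with an estimated correlation.

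Of 63 measured mitotic genes, 5 fell. PBK, a mitotic kinase, fell by 0.80 (SE 0.06), KIF14, a kinesin of cytokinesis, by 0.63 (SE 0.11), FOXM1, the transcription factor of the G2/M programme, by 0.51 (SE 0.07) and CKAP2, a spindle protein, by 0.50 (SE 0.06), n = 3 per group. NCAPH, a condensin subunit, was the last of them, at -0.29. The other 58 did not pass, 9 fell when adjusted over the list alone, and 53 had a negative sign. The median was -0.09, and camera placed the list lower (adjusted p = 1.9e-08), with adjusted p = 0.60 with an estimated correlation. Among the list members named here, DTL and PBK alone of the called ones stayed called without each array in turn. The calls of FOXM1, NCAPH, E2F8, RRM2, FANCF, IFI6, CCL2, HMGCS1, INSIG1, ABCC3, CDH2, RBL2 and ESAM were lost whichever array was left out.

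Among 26 measured cohesin and cohesion factors, the group closest to the function studied, none passed over all probe sets. STAG1, a cohesin subunit, was at -0.36 (SE 0.07, limma adjusted p = 0.051) and TIMELESS, of the fork protection complex, at -0.23 (SE 0.05, limma adjusted p = 0.096), and these 2 were lower when adjusted over the list alone. FEN1 was at -0.19 and ESCO2, the cohesin acetyltransferase, at -0.15, with limma adjusted p of 0.18 and 0.24. The list median was -0.07, 18 of 26 members had a negative sign, and camera called the list lower (adjusted p = 0.0099), with adjusted p = 0.60 with an estimated correlation. That call was lost without CONCR siRNA replicate 2 (adjusted p = 0.060), control siRNA replicate 2 (0.054) or control siRNA replicate 3 (0.11), and under a strict signal filter (0.055).

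Repair and histone genes held 1 call. FANCF, an adaptor of the Fanconi core complex, fell by 0.57 (SE 0.10, limma adjusted p = 0.041) and was the 1 call among 33 homologous recombination and Fanconi genes, with 3 lower when adjusted over the list alone. PALB2 was at -0.27, BLM at -0.29 and H2AX at -0.24, none past the threshold over all probe sets. Camera called this list lower (adjusted p = 1.8e-04), with adjusted p = 0.60 with an estimated correlation. None of 12 measured replication-dependent histone genes passed (0 over the list alone), with H2AC21 at -0.27, H2BC14 at -0.28 and H1-4 at -0.21. The histone list was called lower by camera (median -0.15, adjusted p = 0.0058), with adjusted p = 0.60 with an estimated correlation, and the call was lost without CONCR siRNA replicate 2 (adjusted p = 0.060) or control siRNA replicate 2 (0.051).

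Of 32 measured targets of the tumour suppressor p53, 3 rose and 1 fell. PPM1D, a phosphatase that shuts off p53 signalling, rose by 0.44 (SE 0.05), TP53INP1 by 0.73 (SE 0.12) and the death receptor TNFRSF10B by 0.48 (SE 0.08), n = 3 per group. MDM2, the ubiquitin ligase that degrades p53 and itself a p53 target, fell by 0.50 (SE 0.08, limma adjusted p = 0.039). Among the uncalled targets E2F7, an E2F repressor, was at -0.33, GDF15 at 0.52 and CDKN1A, the p21 inhibitor of cyclin-dependent kinases, at 0.33, with limma adjusted p of 0.050, 0.058 and 0.12. The other 28 did not pass, against 13 higher and 2 lower when adjusted over the list alone, and 29 had a positive sign. The median was 0.14, and camera called the list higher (adjusted p = 1.4e-07), with adjusted p = 0.44 with an estimated correlation.

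Of 31 measured regulators of apoptosis, 4 rose and 2 fell. MCL1, an anti-apoptotic BCL2 family member, rose by 0.48 (SE 0.05), and the TRAIL receptors TNFRSF10D, a decoy, and TNFRSF10A, a death receptor, by 0.52 (SE 0.06) and 0.50 (SE 0.07), beside TNFRSF10B above, n = 3 per group. CYCS, cytochrome c, fell by 0.62 (SE 0.08) and CASP2 by 0.43 (SE 0.07). The other 25 did not pass, with 8 higher and 2 lower when adjusted over the list alone. Camera called the list higher (median 0.09, adjusted p = 0.0030), with adjusted p = 0.44 with an estimated correlation. Both anti-apoptotic and pro-apoptotic genes are among those that rose.

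Interferon-stimulated genes gave 1 rise and 1 fall among 26 measured. IFI6 rose by 0.36 (SE 0.06) and IFIT5 fell by 0.49 (SE 0.07), while SAMD9L was at 0.49 and HERC6 at 0.23 without passing over all probe sets. Adjusted over the list alone, 4 were higher and 2 lower. The list was called higher by camera (median 0.07, adjusted p = 0.0068), with adjusted p = 0.44 with an estimated correlation. It was not called under a strict signal filter (adjusted p = 0.19).

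Stress response and sterol genes held 4 calls. Among 28 targets of NRF2, the regulator of the oxidative stress response, the transporter ABCC3 fell by 0.46 (SE 0.06) and the cytochrome CYP4F11 by 0.41 (SE 0.06). GCLC, of glutathione synthesis, was at -0.26 and OSGIN1 at -0.32, and 7 members were lower when adjusted over the list alone. Camera called this list lower (median -0.09, adjusted p = 4.8e-04), with adjusted p = 0.60 with an estimated correlation. Among 20 sterol synthesis genes, HMGCS1 rose by 0.42 (SE 0.07) and INSIG1 by 0.34 (SE 0.06), while IDI1 was at -0.38 and STARD4 at 0.36 without passing, with 3 higher and 1 lower when adjusted over the list alone. The sterol list was at the threshold in camera (median 0.05, adjusted p = 0.048), with adjusted p = 0.60 with an estimated correlation, and lost its call without CONCR siRNA replicate 1 (0.11), CONCR siRNA replicate 2 (0.060), control siRNA replicate 1 (0.14) or control siRNA replicate 3 (0.090), under median centring (0.059) and with array weights (0.11).

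**Figure D3:**
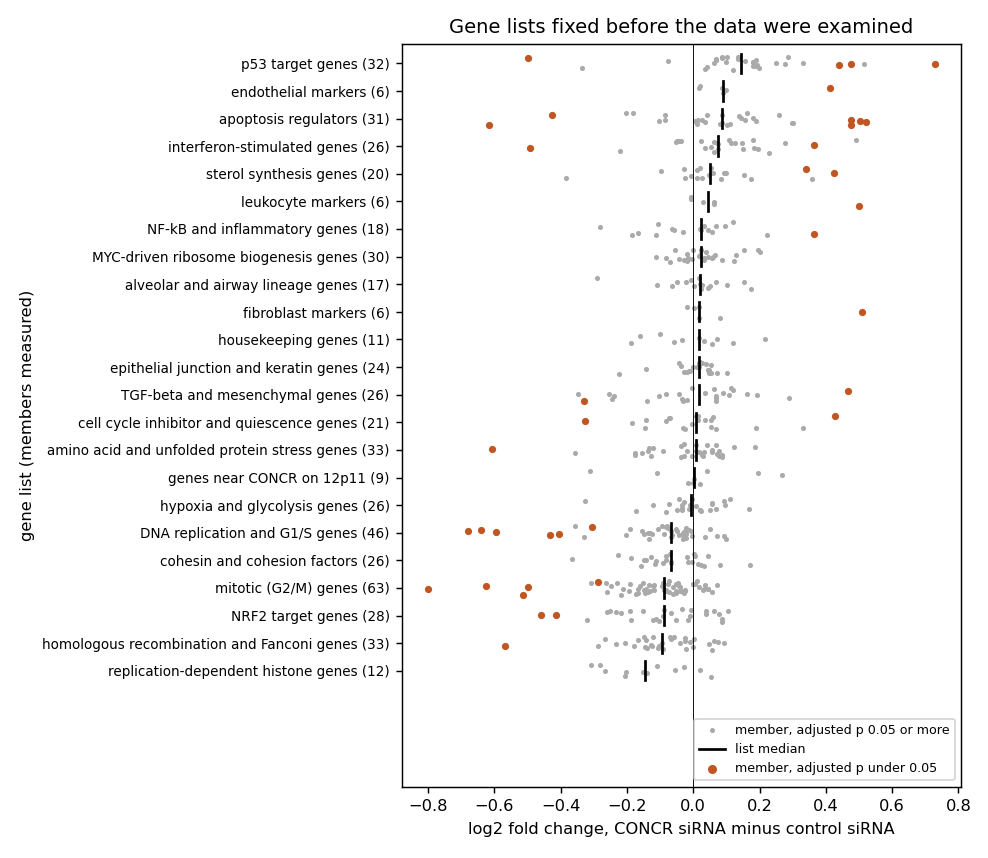
Log2 fold change (horizontal axis) of each measured member of 23 gene lists (vertical axis, with the number measured), with orange points for members past an adjusted p of 0.05 and black bars for list medians. Medians run from -0.15 for histone genes to 0.14 for p53 targets.

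The remaining lists were not called by camera, and some held called genes. SLC7A5, the leucine transporter, fell by 0.61 (SE 0.07) as the 1 call among 33 amino acid and unfolded protein stress genes (camera adjusted p = 0.35, 1 over the list alone), where HERPUD1 was at -0.36, DDIT4 at -0.18 and ATF4 at -0.16. The chemokine CCL2 rose by 0.36 (SE 0.06) as the 1 call among 18 NF-kB and inflammatory genes (camera adjusted p = 0.96), and LIF was at -0.28, TNFAIP2 at -0.19 and NFKBIA at 0.22. Over that list alone 1 was higher and 1 lower. ITGA5, an integrin, rose by 0.47 (SE 0.06) and CDH2, N-cadherin, fell by 0.33 (SE 0.06) among 26 TGF-beta and mesenchymal genes (camera adjusted p = 0.96), with 3 higher and 4 lower over the list alone, and TPM1 at -0.25 and CCN1 at 0.29. GADD45A, a stress-induced gene, rose by 0.43 (SE 0.06) and RBL2, the pocket protein p130, fell by 0.33 (SE 0.06) among 21 cell cycle inhibitor and quiescence genes (camera adjusted p = 0.96, 2 higher and 1 lower over the list alone).

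No member passed over all probe sets among 26 hypoxia and glycolysis genes (camera adjusted p = 0.96, 1 lower over the list alone), where CA12 was at -0.33, HK2 at 0.17 and NDRG1 at -0.17. The same held for 24 epithelial junction and keratin genes (camera adjusted p = 0.96, 0 over the list alone), with CDH1 at -0.22 and ELF3 at -0.14. It held for 17 alveolar and airway lineage genes (camera adjusted p = 0.72, 0 over the list alone), with MUC5AC at -0.29, CAV1 at 0.15 and FOXA1 at 0.18. It held for 30 ribosome biogenesis genes driven by MYC (camera adjusted p = 0.35, 0 over the list alone), with WDR12 at 0.20, NOP2 at 0.20, RCL1 at 0.15 and NOLC1 at 0.12. Among 11 housekeeping genes (camera adjusted p = 0.96, 0 over the list alone), POLR2A was at 0.22, GAPDH at -0.19, TBP at -0.16 and B2M at 0.12. Genes near CONCR had a camera adjusted p of 0.96. For stress, TGF-beta and housekeeping genes the list median was above 0 and the mean below 0, and camera pointed lower for stress, housekeeping and cell cycle inhibitor genes against medians above 0.

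Markers of other cell types were measured beside these. PDGFRA rose by 0.51 (SE 0.05) among 6 measured fibroblast markers, CD68 by 0.50 (SE 0.06) among 6 leukocyte markers and ESAM by 0.41 (SE 0.06) among 6 endothelial markers. In each of these lists the other 5 markers did not pass over all probe sets or over the list alone. The lists were not called, with camera adjusted p of 0.20 for fibroblasts, 0.17 for leukocytes and 0.060 for endothelium. The endothelial list was called without control siRNA replicate 1 (adjusted p = 0.033) and with array weights (0.036).

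In all, camera called 10 of the 23 lists, 4 higher and 6 lower. With an estimated correlation it called 0, and 1 list, p53 targets, had an unadjusted p under 0.05 (0.021). Fry called 4, namely replication and G1/S genes lower (adjusted p = 0.033) and p53 targets (0.031), apoptosis regulators (0.037) and interferon-stimulated genes (0.037) higher.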

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

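The tests of arrays exchanged between the groups, of probe sets past 1.5-fold and of probes shared between metallothionein copies were chosen only after the result was seen, as were the rules that void the background test and the metallothionein test without 1 array. Outside the comparison, 3 of 2246 control probe sets with enough signal passed limma's adjusted p of 0.05, and 221 had an unadjusted p under 0.05. One numbered control probe set was higher with CONCR siRNA by 1.37 (SE 0.15, adjusted p = 0.047), with means of 6.37 and 4.99, and it stands out because it moved in data that the report does not use. PSR02030746.hg.1 and PSR02030747.hg.1 were lower, by a log2 change of -1.08 and -1.06. The transcripts these probe sets read are not named here.

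More probe sets were lower than higher, 488 against 125. The share of lower calls was at least 71.6% under quantile normalization and median centring. The deposited values were already quantile normalized, so scaling them again cannot test that first step, and scaling stays undecided. Leaving out 1 array left at least 84.5% lower, among 129 to 411 calls. This argues against 1 array as the cause for the calls still made, and calls that were lost are not covered. Gene length met the bound set beforehand for a cause, because a length correction, itself added after the data were seen, left 58.9% of calls lower. But the same probe sets stood at 67.0% before it, already under the 70% that would have counted against length. So part of the excess may follow length (Spearman's rho across genes -0.11, and genes are not independent replicates). Past 1.5-fold the share of lower calls was 92.9% before the length correction and 90.9% after it. The correction takes out only a smooth trend on length and could hardly undo changes this large. It therefore does not exclude length for these falls. At least 92.2% of calls past 1.5-fold were lower under the other scalings, with the same limit as above. Whether these deep falls follow from loss of CONCR or from other RNAs silenced by the same siRNAs stays open, as siRNA and transcript sequences were not used here.

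CONCR itself differed by only -0.23. Its control signal lay 6.28 below the brightest background probe set (-6.28), inside the background range as a dim signal would, but 99.4% of tested probe sets lie inside that range too, so this test is void and a floor on the CONCR signal cannot be told apart from a small knockdown. Among 5360 probe sets within 0.25 log2 units of the CONCR mean, 30 were called, 25 of them lower, none by 2-fold and the deepest by -0.81. The deepest CONCR change under any exchange of 1 or 2 arrays of each group was again -0.23, with replicate 3 of both groups exchanged. The labelled grouping already had the smallest possible exact permutation p of 0.1, so no exchange could go deeper. The exchange test therefore decides nothing about exchanged arrays, and a single wrong label was not tested. It was the last of 3 tests tried, and the 2 before it were undecided as well. In the first, 6 arrays correlated best with their own group over tested clusters but 5 over all clusters. In the second, exchanging replicate 1 of both groups gave 3981 probe sets at an unadjusted limma p under 0.05, against 4146 for the real grouping. At limma's adjusted p of 0.05 the same exchange called 0 probe sets, against 613 for the real grouping. With 10 groupings in all, no share under 0.05 was possible.

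Metallothionein genes, small metal-binding proteins, had positive changes as a family, a pattern noticed in the data. All 13 probe sets had a positive log2 change, with a median of 0.42, and 1 passed limma's adjusted p (MT2A, 0.56). If the probes of every copy read 1 transcript equally well, all should move like MT2A. Of the probe sets, 4 lay below it by more than 2 standard errors, MT1X at 0.08 among them. MT2A was the brightest, at a mean of 10.2 against 8.0 for MT1X and 5.1 for MT1M. A dimmer probe set that reads MT2A only weakly could also move less, so the test does not decide whether probes are shared. Without any 1 array at least 92.3% of the probe sets stayed above 0, which decides nothing because the family was picked for its signs. For the same reason no test of the family as a set is given, and whether CONCR loss or these siRNAs lie behind it was not tested.

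Other groupings of the 6 arrays into 3 and 3 number 10 with the real one, too few for a share under 0.05. The real grouping called 613 probe sets and the highest other 1. For the lists the real grouping called 10 and the highest other 8. Replication genes and mitotic genes were each called in 5 of the 9 other groupings, p53 targets in 5, and interferon-stimulated genes and apoptosis regulators in 0. Some other groupings gave a camera p as small as the real one, 3 for cohesin genes and 2 each for mitotic, histone, homologous recombination and sterol genes, and the lowest adjusted p among them was 2.5e-12 for mitotic genes against 1.9e-08 in the real grouping.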

How the results depend on the processing

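The length correction and leaving out each array for the lists were chosen after the data were seen. The main fit made 613 calls, 125 higher and 488 lower. The higher calls alone moved by more than 1.5 times under quantile normalization (213) and median centring (65). The total stayed within 1.5 times under quantile normalization (749), median centring (432), array weights (794) and the log odds (540). It moved to 238 (36 higher, 202 lower) with no filter, where 67528 sets are adjusted for, 1102 (342 higher, 760 lower) under the strict filter, 965 (252 higher) with an intensity trend and robust estimation, 169 (37 higher, 132 lower) without moderation, 174 (10 higher, 164 lower) with a 1.5-fold minimum and 958 (304 higher) with 1 set per gene; the cause was not tested beyond what each does. Restricting to the 16365 sets with a gene length gave 959 (643 lower), and the length correction moved that to 1031 (424 higher, 607 lower). Without 1 array, with fewer samples, it ran from 129 to 411 (11 to 56 higher, 109 to 355 lower), and all 613 kept their sign. The labels do not say whether a replicate number marks a shared day or culture. Correlations of deviations of same-numbered arrays were -0.27, -0.16 and -0.08, and not every array correlates best with its own number. The arrays were therefore treated as unpaired, although so few arrays cannot exclude a pairing. With the number as a block 51 were called (4 higher, 47 lower) and 10 lists. CONCR was not called under any alternative that measured it (-0.32 to -0.12 without 1 array), and has no value under the strict filter; nor was DDX11 (-0.03 to 0.00). List counts were 8 to 10 under other settings and 7 to 10 without 1 array (3 to 4 higher, 4 to 6 lower), 0 with an estimated correlation (0 higher, 0 lower) and 4 with fry (3 higher, 1 lower); camera was not run with the unmoderated statistic. Of 76 called genes named in the text, all kept their sign, and 62 were not called with the block, 54 lost the call without moderation, 35 with no filter, 17 under median centring, 2 under quantile normalization and 0 with array weights or the intensity trend. Whether signal over background limits the CONCR value was not settled.

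The direction of camera turned for some lists that were not called either way, and the values are list medians minus that of other genes. They were -0.0070 for NF-kB genes and -0.038 for genes near CONCR with array weights. For TGF-beta genes they were 0.0043 with the replicate block or the intensity trend, 0.0053 with no filter, -0.044 under the strict filter and 0.00098 with array weights. For cell cycle inhibitor genes they were 0.0033 with no filter and 0.010 under quantile normalization. For housekeeping genes they were 0.012 under the strict filter, 0.019 under quantile normalization and 0.0063 with the intensity trend. With fry the direction also differed for genes near CONCR, cell cycle inhibitors and housekeeping genes. Their values in the main fit were -0.010, -0.0032 and 0.0063, as fry gives no such value of its own. Without 1 array they ran from -0.022 to 0.027 for NF-kB, -0.026 to -0.0039 for hypoxia, -0.0042 to 0.021 for TGF-beta, -0.011 to 0.012 for epithelial, -0.0031 to 0.040 for alveolar, -0.041 to 0.020 for genes near CONCR, -0.040 to 0.011 for cell cycle inhibitor and -0.0064 to 0.022 for housekeeping genes. The cause was not tested.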

Other observations

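The genes of this part were chosen after their values were seen. The 2 kinases of the Mediator kinase module fell together, CDK19 by 0.80 (SE 0.07, limma adjusted p = 0.0044) and CDK8 by 0.74 (SE 0.08, limma adjusted p = 0.0096), n = 3 per group. The Y RNA RNY1 was lower by a log2 change of -0.60 (SE 0.10) and RO60, the protein that binds Y RNAs, by -0.55 (SE 0.07), with limma adjusted p of 0.041 and 0.016. Of 765 genes listed as long noncoding RNA, 5 were called (0.65%, against 2.61% of all genes with 1 probe set each). NORAD was 1 of them, at -0.66 (SE 0.11, limma adjusted p = 0.035). TUG1, a long noncoding RNA listed as protein-coding in the gene table, was at -0.29 (SE 0.05, limma adjusted p = 0.043). EGFR, the epidermal growth factor receptor, fell by 0.43 and CDK4, the G1 kinase, by 0.50, while the hyaluronan receptor CD44 rose by 0.45 and the interleukin receptor gene IL6R by 0.33. CDK19 was called without each array in turn. EGFR, IL6R and TUG1 lost the call whichever array was left out, and the other genes of this paragraph lost it without at least 1 array.

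Several genes fell together with a pseudogene copy. RHOQ fell by 0.77 (SE 0.09) and RHOQP2 by 0.72 (SE 0.09), RSU1 by 0.39 (SE 0.05) and RSU1P1 by 0.50 (SE 0.06), SHLD2, of the shieldin complex, by 0.91 (SE 0.07) and SHLD2P3 by 0.63 (SE 0.09), and the transporter gene SLC7A5 by 0.61 (SE 0.07) and SLC7A5P1 by 0.44 (SE 0.06). Probe sequences were not used here, and the members of each pair are uncertain as separate measurements. SHLD2 was called without each array in turn. RSU1 lost the call whichever array was left out, and the other genes of the pairs lost it without at least 1 array.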
